A study of Mus musculus with 8 samples.

How the data were processed

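RNA from colonic epithelial cells of 4-week-old mice was sequenced in 8 libraries, 4 labelled Ccna2-KO (Ccna2 flanked by Cre sites, villin-driven Cre) and 4 control (the same sites without Cre). Groups and replicate numbers were taken from the sample labels. Per the labels, libraries were prepared with standard Illumina protocols, and the design text names an Illumina sequencer. The deposited values are estimated counts per RefSeq transcript. Per the submitters' processing notes, kallisto and the mouse build GRCm38 (mm10) were used, and the kallisto version is not given in the sources used here. Kallisto assigns reads to transcripts by compatibility and shares reads that fit several transcripts between them, so values of near-identical genes are uncertain. No exon counts were used, and strandedness of the libraries is not given in the sources used here.

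The table held 107193 transcripts and 35963 gene symbols. Of these transcripts, 687 carried no symbol and made up 3.19% to 5.51% of the counts, mostly the ribosomal RNA Rn28s1. They were left out of library sizes and gene tests and were tested separately. Estimated counts were summed per symbol and rounded to whole numbers. The gene totals then ranged from 25960180 to 33028486 per library. All library pairs differed by more than sampling noise, so no library repeated the counts of another. Each library counted as 1 replicate after its label, which does not show that the libraries came from separate mice.

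The test was edgeR 4.0.16 in R 4.3.3, with its default filter on low counts, TMM scaling, robust dispersion estimates and the quasi-likelihood F test of genotype over all 8 libraries, with no covariate. P-values were adjusted by Benjamini and Hochberg over the 15893 genes kept, with a threshold of 0.05. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Standard errors belong to log2 fold changes and SDs to 4 libraries. On data simulated from these libraries (15614 genes run), 61% of 100 genes changed by 1 on the log2 scale and 96% of 100 genes changed by 2 were recovered, and 6.5% of calls were false. That simulation drew each gene independently. In it 0 of 32 unchanged lists were called, which does not test list calls among correlated genes. An exact two-sided permutation test compared single values, 4 libraries against 4. A gene with at most 3 counts over a group is given as a ratio with its counting interval, which covers counting error only.

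Before the data were examined, 34 gene lists were written for the cell cycle, DNA damage, p53, Wnt and YAP targets, colonic cell types, other cells an isolate can hold, neighbouring gut regions, inflammation, stress and metabolism. The list of mitochondrially encoded genes had fewer than 5 tested members, and 33 lists were tested. The tests were limma 3.58.1 camera with a preset correlation of 0.01, adjusted over the lists, and, as alternatives, camera with an estimated correlation and fry. "Adjusted over the list alone" means that adjustment used only the genes of that list. A list mean is the mean of log2 CPM after each gene was centred over the 8 libraries. A further 7 lists were chosen after seeing the data.

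Genes were named by a rule fixed before the data were examined. It takes Ccna2 and, whatever their values, Ccna1, Ccnb1, Ccne1, Ccnd1, Cdk1, Cdk2, Mki67, Cdkn1a, Lgr5, Krt20, Muc2, Epcam and Ptprc. It adds the 10 largest and 10 smallest log2 fold changes among genes with adjusted p under 0.05, a mean log2 CPM of at least 1, groups that do not overlap and a proper symbol. It also adds the 3 members with the smallest adjusted p in each called list and at most 2 passing members in each other list. Some genes that the rule takes are not reported here. Coordinates are from the RefSeq annotation of GRCm38, and the exon number of Ccna2 from GENCODE on the same build.

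The alternatives fixed before the data were examined were RLE and upper quartile scaling, no filter, a stricter filter of 1 CPM in all libraries of a group, DESeq2 1.42.0, limma voom, non-robust estimates, replicate number as a covariate, a 2-fold minimum, tests of single transcripts, and leaving out each library. After seeing the data, a term for the library number set was added to the fit. The library numbers in the labels were divided at their widest gap into a low and a high set. This was done because the division of the libraries along these numbers had changed as many genes as genotype. The set term is estimated from 8 libraries in which set and genotype overlap in 6, so the effects are only partly separable. With the term, the SE of the genotype effect fell for some genes, such as Rrm2 (0.36 to 0.15). It rose for others, such as Cd74 (0.89 to 1.30). List counts with single libraries left out were also added after seeing the data.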

Results

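RNA was sequenced from colonic epithelial cells released with a chelating buffer from the proximal colon of 4-week-old mice. The 4 libraries labelled Ccna2-KO came from mice in which both copies of Ccna2 carried sites for Cre recombinase and Cre was driven by the villin promoter, which is active in intestinal epithelium. The 4 control libraries came from mice with the same sites and no Cre. Ccna2 encodes cyclin A2, a partner of the cyclin-dependent kinases in S phase and at entry into mitosis. The comparison asks which transcripts differ in the colonic epithelium when the gene is targeted there. Each library held between 27162083 and 34386731 estimated counts. The labels name 1 library per replicate and do not state that each came from a separate mouse, so p-values measure the spread between these libraries.

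The Ccna2 count did not separate the groups. Ccna2 lies on chromosome 3 between positions 36564865 and 36573038 (GRCm38), on the minus strand, and its principal annotated transcript has 8 exons. The controls held 1557, 648, 387 and 605 counts and the libraries labelled Ccna2-KO held 541, 886, 853 and 414. After scaling, the means were 27.6 ± 18.7 and 21.9 ± 5.46 CPM (counts scaled to the size of the library; SD, n = 4 each), and the log2 fold change was -0.33 ± 0.41 (SE; edgeR adjusted p = 0.673). An exact two-sided permutation test of log2 CPM gave p = 0.83, where 0.0286 is the smallest value that 4 against 4 can give. Control replicate 1 held the highest level, 54.3 CPM, and without it the log2 fold change was 0.24. With a term for the library number set of the labels, it was -0.71 ± 0.30 (adjusted p = 0.133). The targeted exons are not given in the sources used here and the counts are per transcript, so reads from exons outside the deleted part cannot be separated from the rest. The groups are therefore called by their labels, and every direction given rests on those labels.

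Many genes nevertheless differed between the labelled groups. Of 15893 genes tested, 1924 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1017 higher and 907 lower in the libraries labelled Ccna2-KO. Among these, 650 were higher and 481 lower by at least 2-fold. All 4 values of one group lay outside the range of the other in 3021 of all genes tested (19.0%), against 2.86% by chance for an unchanged gene, and in 1771 of the 1924. Leaving out single libraries gave between 972 genes (without Ccna2-KO replicate 3) and 4627 (without control replicate 1). The first principal component held 49.9% of the variance and placed all controls on one side of 0 and all libraries labelled Ccna2-KO on the other. The second held 23.8% and set control replicate 1 apart from the other 7 libraries, with a score of 74.2.

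A second division of the libraries overlapped with genotype. The labels number the libraries, and these numbers form a low set (595 to 598) and a high set (621 to 641). The low set held 3 controls and Ccna2-KO replicate 4, and the high set held control replicate 1 and the other 3 libraries labelled Ccna2-KO. What the numbers stand for is not given in the sources used here. Dividing the libraries along these sets and ignoring genotype changed 1949 genes, about as many as genotype did. Each set held a single library of one group, so no test within a set was made. With a term for the set in the fit, an analysis chosen after seeing the data, 2892 genes changed with genotype, 1477 higher and 1415 lower. Of the 1924 genes, 1636 still passed and 0 changed direction, and the median ratio of their log2 fold changes with and without the term was 0.92. With genotype in the fit, 3548 genes differed between the sets. This rests on control replicate 1 against the other controls and Ccna2-KO replicate 4 against the rest of its group. Effects of these single libraries therefore cannot be told from a set effect, here or in the list tests between the sets. Values with the set term are called set-adjusted and are given beside part of the results.

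**Figure D1:**
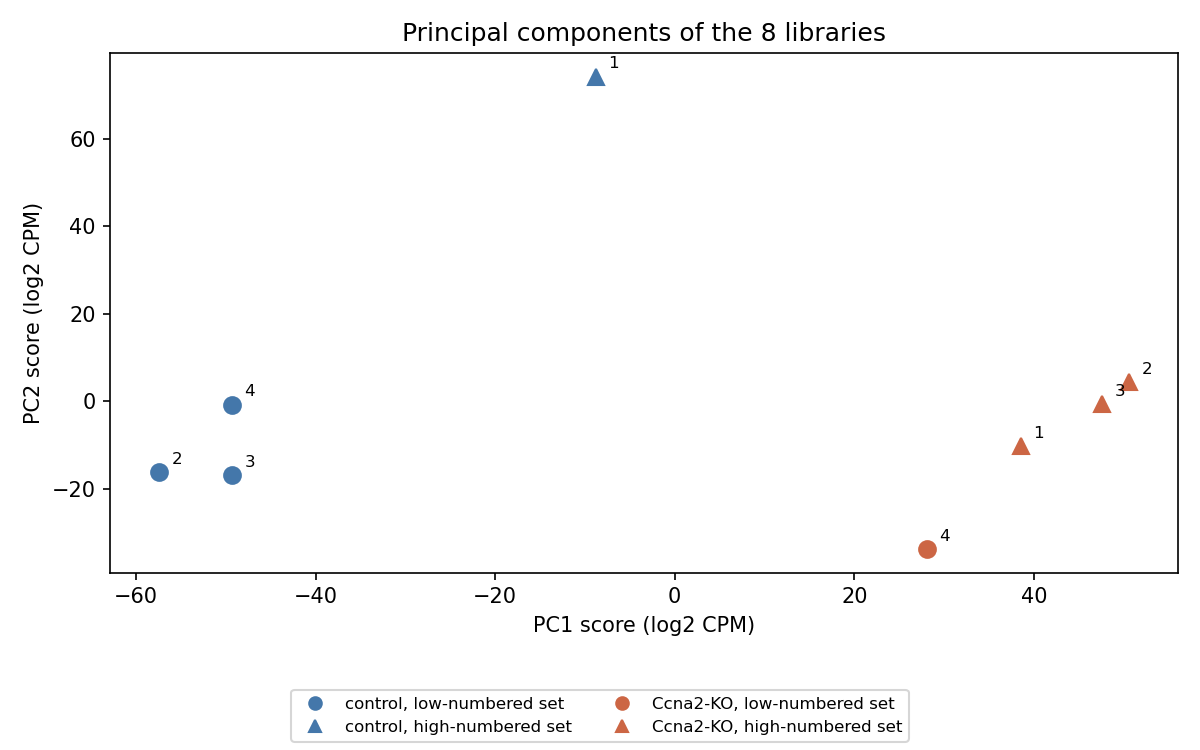
Scores of the 8 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, numbered by replicate, with colour for the group and marker shape for the library number set. The components hold 49.9% and 23.8% of the variance, and control replicate 1 has a second-component score of 74.2.

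Genes of cell division were higher in the libraries labelled Ccna2-KO. Mki67, a marker of cycling cells, rose from 96.4 to 283 CPM (log2 fold change 1.55 ± 0.20 SE, adjusted p = 0.00182). Ccne1, the G1/S cyclin E1, rose by 2.11 ± 0.35 (adjusted p = 0.00563) and Rrm2, a subunit of ribonucleotide reductase, by 2.85 ± 0.36 (adjusted p = 0.00184). Of 50 mitosis genes, 25 rose and 1 fell (42 and 1 adjusted over the list alone), with a median log2 fold change of 1.08. Top2a, which untangles DNA, rose by 1.65 ± 0.27, and Casc5, a kinetochore scaffold now named Knl1, by 1.19 ± 0.17. Of 42 DNA replication genes, 12 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.87. Pola2, a subunit of DNA polymerase alpha, rose by 0.80 ± 0.11. Ccnb1 (1.14 ± 0.34, adjusted p = 0.0565) and Cdk1 (1.21 ± 0.39, adjusted p = 0.0757) did not pass, and their set-adjusted p-values were 0.037 and 0.021. The log2 fold changes of Cdk2 and Ccna1 were 0.19 ± 0.20 and 0.30 ± 0.40, neither passing, and both were negative after set adjustment, at -0.10 and -0.11.

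The camera test called both division lists (adjusted p = 2.41e-16 for mitosis and 6.20e-12 for replication). Neither call held with an estimated correlation (adjusted p = 0.443 for each). Control replicate 1 lay near the libraries labelled Ccna2-KO on both lists. Its mitosis mean was 0.31 on the centred log2 scale, against -0.61 to -0.98 in the other controls. The libraries labelled Ccna2-KO had 0.22 to 0.81, and an exact permutation test of these mitosis means gave p = 0.0571. The replication mean of control replicate 1 was 0.43, against -0.87 to -0.77 in the other controls. The libraries labelled Ccna2-KO had replication means of 0.07 to 0.79, so the groups overlapped on both lists. Without this library 47 mitosis genes and 41 replication genes rose, but the 3 controls left then all came from the low set. Without any 1 of the other 7 libraries, 10 to 24 mitosis genes and 6 to 11 replication genes rose. Both lists also differed between the number sets, higher in the high set (adjusted p = 3.83e-14 and 3.31e-15). Set-adjusted medians were 0.75 for mitosis, with 30 genes higher, and 0.50 for replication, with 16 higher.

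**Figure D2:**
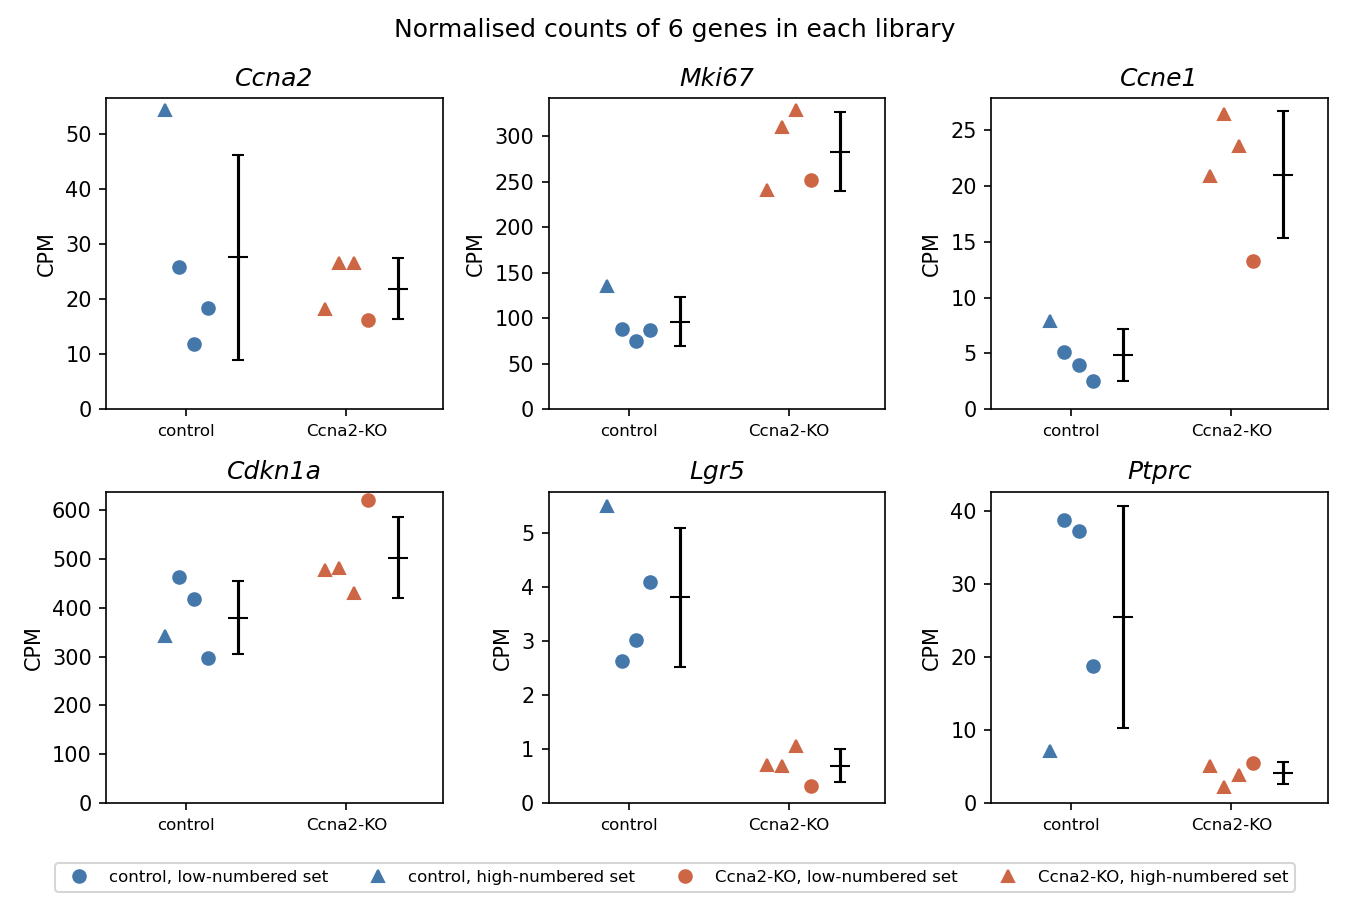
Normalised counts (CPM, y axis) of 6 genes in each library, by labelled group (x axis), with bars for the mean ± SD of 4 libraries and marker shape for the number set. The Ccna2 values of the groups overlap, whereas Mki67 averages 96.4 CPM in the controls and 283 CPM in the libraries labelled Ccna2-KO.

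Cyclins and their inhibitors moved in both directions. Among 34 genes of cyclins, their kinases and inhibitors, 10 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.39; camera adjusted p = 0.000377; adjusted p = 0.442 with an estimated correlation). The list also differed between the number sets (adjusted p = 0.00201). Its median was 0.18 after set adjustment and 0.82 without control replicate 1. Ccnd2 rose by 0.86 ± 0.09 and E2f7, a repressor of E2F target genes, by 2.92 ± 0.31. Cdkn2a, which encodes the inhibitor p16 and the p53 activator p19Arf, rose from 0.035 to 1.44 CPM (5.25 ± 0.64, adjusted p = 0.00159). Ccnd1 rose by 0.67 ± 0.16 (adjusted p = 0.0266), a call that ended after set adjustment (0.50, adjusted p = 0.061) and without any 1 of 6 libraries, all but control replicate 1 and Ccna2-KO replicate 4 (adjusted p up to 0.0695). Cdkn1a, which encodes p21, had a log2 fold change of 0.40 ± 0.17 that did not pass (adjusted p = 0.165), and set-adjusted it was 0.55 (adjusted p = 0.035).

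Genes of DNA repair and targets of p53 were also higher. Of 58 genes of the DNA damage response and repair, 23 rose and 1 fell (23 and 4 adjusted over the list alone), with a median of 0.40. With single libraries left out, 12 (without Ccna2-KO replicate 3) to 33 (without control replicate 1) rose and 0 to 5 fell. Brca1, of homologous recombination, rose from 5.46 to 24.8 CPM (2.19 ± 0.22, adjusted p = 0.000626). Polq, the polymerase of end joining by microhomology, rose by 1.65 ± 0.18 and Fanca, of the Fanconi anaemia complex, by 1.86 ± 0.27. Of 41 p53 targets, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.27. Eda2r, a receptor of the tumour necrosis factor family, rose by 3.56 ± 0.37, Ddit4l by 3.75 ± 0.47 and Ccng1, cyclin G1, by 0.94 ± 0.12. The p53 list mean lay between -0.38 and -0.24 in the controls and between 0.22 and 0.37 in the libraries labelled Ccna2-KO. The repair list means of the groups overlapped. Control replicate 1 was at 0.13, the other controls at -0.52 to -0.44 and the libraries labelled Ccna2-KO at 0.09 to 0.49. Camera called both lists (adjusted p = 1.89e-06 for repair and 0.000199 for p53). With an estimated correlation the values were adjusted p = 0.443 and 0.112. The repair list also differed between the number sets (adjusted p = 1.28e-07), and the p53 list did not pass that test (adjusted p = 0.629). The set-adjusted repair median was 0.18, with 22 genes higher and 3 lower.

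Hormone-secreting and tuft cell genes were lower. Chga and Chgb, which encode granins of secretory granules, fell from 74.9 to 14.3 CPM (-2.39 ± 0.22) and from 95.0 to 22.7 CPM (-2.07 ± 0.19), with adjusted p of 0.000367 and 0.000352. Tph1, the enzyme of serotonin synthesis in enterochromaffin cells, fell by 2.19 on the log2 scale (SE 0.28). Of 28 enteroendocrine genes, 12 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.98; camera adjusted p = 6.66e-06; adjusted p = 0.315 with an estimated correlation). Without control replicate 1, 12 enteroendocrine genes fell and 5 rose, and without any 1 of the other libraries 1 rose. Trpm5, a cation channel of tuft cell signalling, changed by -2.75 ± 0.33 and Plcb2, a phospholipase of the same pathway, by -1.92 ± 0.29. Of 23 tuft cell genes, 13 fell and 1 rose (16 and 1 adjusted over the list alone; median -1.45; camera adjusted p = 1.75e-08; adjusted p = 0.315 with an estimated correlation). Several of those that fell, such as Vav1 (-1.46 ± 0.18), are also expressed by leukocytes, of which the T cell genes fell as well.

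Stem cell, goblet cell and absorptive cell genes did not move as groups. Lgr5, a receptor that marks crypt base stem cells, fell from 3.81 to 0.69 CPM (-2.44 ± 0.38, adjusted p = 0.00436). Among 20 stem cell genes, 3 fell and 2 rose (3 and 2 adjusted over the list alone), with a median of 0.04, a mean of -0.41 and a camera direction that was lower. Bmi1 rose by 0.85 ± 0.12, and Nrn1 had 112 counts over the controls and 3 over the libraries labelled Ccna2-KO, a ratio of 0.0265 (95% counting interval 0.00538 to 0.0795). The stem cell list was not called (camera adjusted p = 0.404), but it was lower after set adjustment (adjusted p = 0.0184, 7 fell and 2 rose). Muc2, the main colonic mucin, had a log2 fold change of -0.13 ± 0.29 (adjusted p = 0.834). Of 31 goblet cell genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; median -0.08; camera adjusted p = 0.974, with its direction higher), and set-adjusted 10 fell and 2 rose (adjusted p = 0.00725). Without control replicate 1, 6 goblet cell genes rose, without Ccna2-KO replicate 4, 4 did, and without any 1 of the other 6 libraries 0 did, while 0 or 1 fell. Krt20, of differentiated surface cells, changed by 0.31 ± 0.21 (adjusted p = 0.399). Of 39 colonocyte genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone; median 0.16; camera adjusted p = 0.233), and the list was called after set adjustment (adjusted p = 0.0345, 10 rose and 4 fell) and without control replicate 3 (adjusted p = 0.0389). Between 0 (without Ccna2-KO replicate 3) and 5 (without control replicate 1) colonocyte genes rose, and 1 to 3 fell, with single libraries left out. Epcam, found throughout the epithelium, averaged 1884 and 1928 CPM (0.03 ± 0.10, adjusted p = 0.882).

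Genes typical of the small intestine and of fetal-like epithelium were higher. Sis, the brush border enzyme sucrase-isomaltase, rose from 5.97 to 34.95 CPM (2.55 ± 0.32, adjusted p = 0.00184) and Npc1l1, a sterol transporter, by 1.95 ± 0.31. Of 16 small intestinal genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone; median 1.20; camera adjusted p = 7.55e-06; adjusted p = 0.315 with an estimated correlation). Of 25 genes of fetal-like and regenerating epithelium, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.64; camera adjusted p = 5.18e-05; adjusted p = 0.238 with an estimated correlation). Gja1, connexin 43, rose by 3.28 ± 0.32 and Sprr1a, a cornified envelope protein, by 1.42 ± 0.13. Of 14 Paneth-like and deep crypt secretory genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.52; camera adjusted p = 0.0836; set-adjusted, 5 rose and 4 fell). Between 3 and 7 genes of this list rose and 1 fell with single libraries left out. Mmp7, a protease that activates defensins, rose by 4.86 ± 0.55, and Dll1, a Notch ligand, fell by 1.66 on the log2 scale (SE 0.16). The distal colon list (9 genes, 3 higher and 1 lower, 4 and 1 adjusted over the list alone) was not called (camera adjusted p = 0.114). Wnt targets (22 genes, 3 higher and 2 lower, 7 and 3 adjusted over the list alone; adjusted p = 0.248) and YAP targets (22 genes, 4 higher and 3 lower, 4 and 6 adjusted over the list alone; adjusted p = 0.159) were not called either. Without control replicate 1, 8 Wnt targets rose and 4 fell, and 4 YAP targets rose and 8 fell. Without any 1 of the other libraries, 2 to 5 and 2 to 4 rose, and 2 to 3 and 3 to 4 fell. With single libraries left out, the Paneth-like list was called without Ccna2-KO replicate 4 (adjusted p = 0.00215) or control replicate 1 (0.0474), the Wnt list without Ccna2-KO replicate 4 (0.035) and the distal colon list without control replicate 3 (0.0480). Axin2 rose by 0.84 ± 0.12 while Cyr61 fell by 1.66 on the log2 scale (SE 0.14).

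T cell genes were lower in the libraries labelled Ccna2-KO. Of 20 genes of T cells and intraepithelial lymphocytes, 19 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -2.57. Camera called the list (adjusted p = 6.20e-12; adjusted p = 0.315 with an estimated correlation). Ccl5, a chemokine of activated T cells, fell from 17.5 to 1.66 CPM (-3.40 ± 0.42, adjusted p = 0.0016). Cd2, an adhesion receptor of lymphocytes, changed by -2.93 ± 0.43. Eomes, a transcription factor, was the gene that rose, from 0.76 to 14.1 CPM (4.19 ± 0.30, adjusted p = 0.000151). Ptprc, which encodes the leukocyte antigen CD45, changed by -2.63 ± 0.51 (adjusted p = 0.0114). Its level was 7.07 CPM in control replicate 1, 18.8 to 38.7 CPM in the other controls and 2.19 to 5.45 CPM in the libraries labelled Ccna2-KO. The set-adjusted change was -1.74 (adjusted p = 0.0493), and the call ended with replicate number as a covariate (adjusted p = 0.0618). The T cell list mean was -0.01 in control replicate 1 and 0.80 to 1.69 in the other controls, against -1.44 to -0.63 in the libraries labelled Ccna2-KO. The list was also lower in the high number set (adjusted p = 0.000179), and its set-adjusted median was -1.93, with 16 genes lower.

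Markers of other cells that an epithelial isolate can hold moved unevenly. Of 21 genes of macrophages, monocytes and dendritic cells, 3 fell and 2 rose (3 and 2 adjusted over the list alone; median -0.38; camera adjusted p = 0.137), with Laptm5 at -2.20 ± 0.51 and Cd68 at 1.13 ± 0.28. Both calls ended after set adjustment, with adjusted p of 0.11 and 0.060, and 2 genes of the list then fell and 0 rose. The list was called lower without control replicate 4 or Ccna2-KO replicate 1 (adjusted p = 0.0341 and 0.0217). The Laptm5 call also ended without control replicate 2 or 3 or Ccna2-KO replicate 3 (adjusted p up to 0.0700), and that of Cd68 without control replicate 2, 3 or 4 or Ccna2-KO replicate 2 or 3 (up to 0.0889). Of 5 B cell genes and 7 neutrophil genes, 0 passed (0 and 3 adjusted over the list alone; camera adjusted p = 0.855 and 0.0607). Of 7 genes of endothelium, glia and neurons, 2 fell, and 2 did so adjusted over the list alone (camera adjusted p = 0.0607; set-adjusted p = 0.0285). The neutrophil list was called higher without control replicate 2 or 3 or Ccna2-KO replicate 2 (adjusted p between 0.0388 and 0.0415), and that of endothelium lower without control replicate 2 or Ccna2-KO replicate 1 (0.0109 and 0.0382). Of 14 fibroblast and smooth muscle genes, 2 rose (2 adjusted over the list alone; median 0.81; camera adjusted p = 0.0231; adjusted p = 0.455 with an estimated correlation), namely Fbln1, a matrix glycoprotein (3.59 ± 0.24), and Des, muscle desmin (2.01 ± 0.36). The set-adjusted camera p for this list was 0.0642, and its call ended without control replicate 1 or 4 or Ccna2-KO replicate 1 (adjusted p up to 0.125). Of 7 red blood cell genes, 1 rose (6 adjusted over the list alone; median 1.71; camera adjusted p = 0.0231; adjusted p = 0.443 with an estimated correlation), and the call ended without control replicate 1 or Ccna2-KO replicate 3 or 4 (adjusted p up to 0.160).

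**Figure D3:**
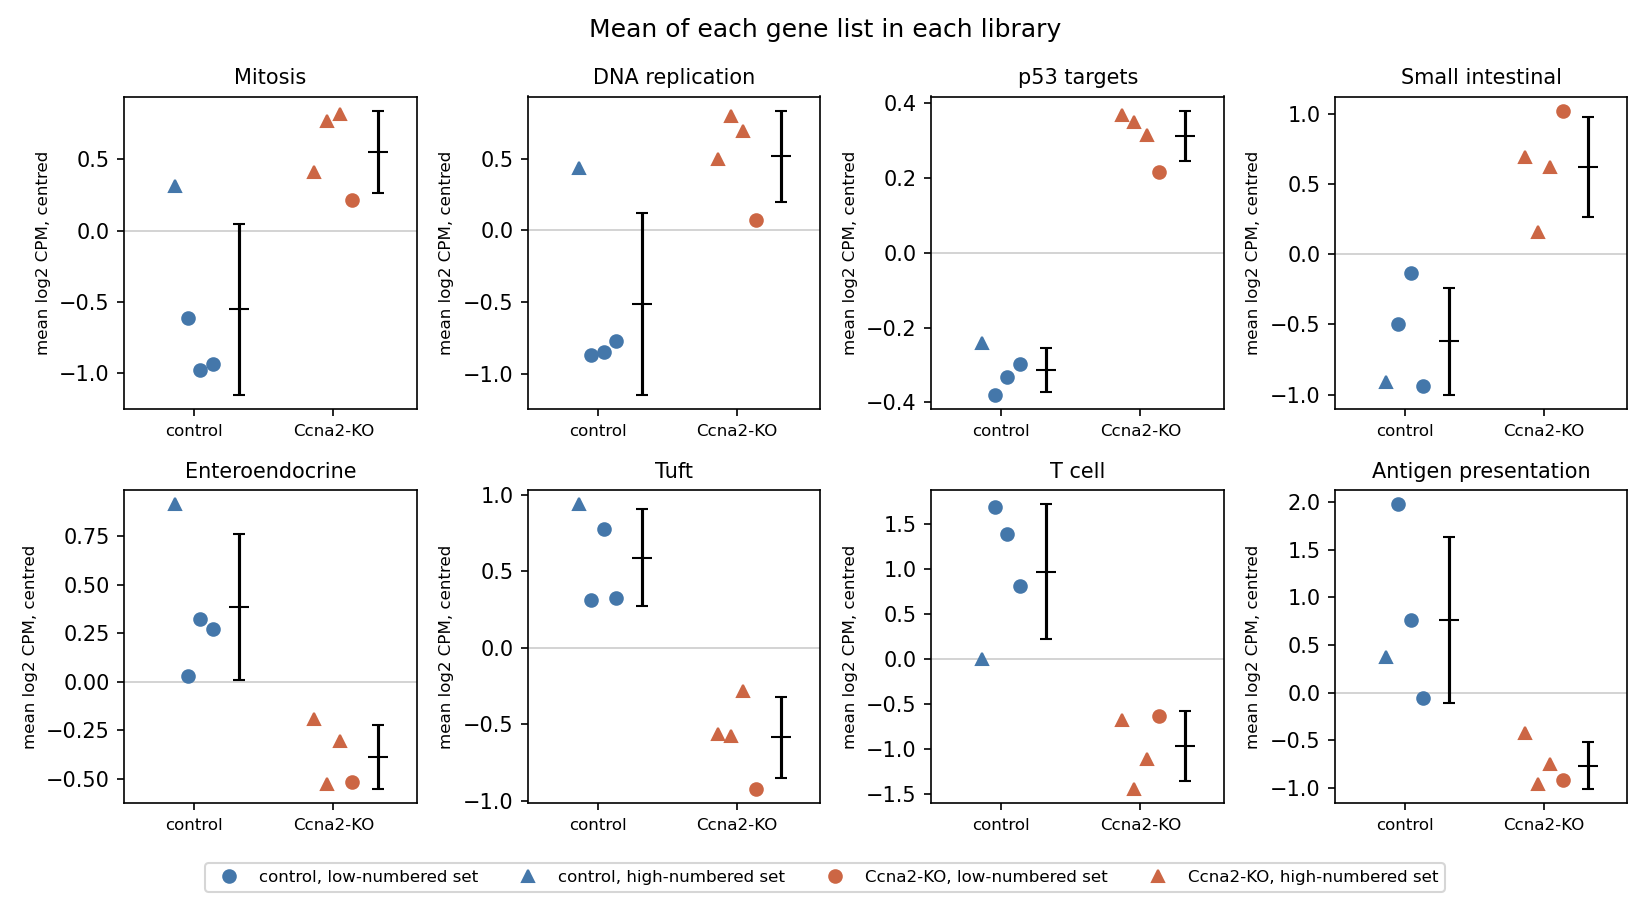
Mean of 8 gene lists in each library (y axis, mean log2 CPM centred on each gene), by labelled group (x axis), with bars for the mean ± SD of 4 libraries and marker shape for the number set. Control replicate 1 has a mitosis mean of 0.31 and a T cell mean of -0.01.

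Antigen presentation genes were lower, led by those of MHC class II. Cd74, the invariant chain, fell from 299.9 to 7.21 CPM (-5.38 ± 0.89, adjusted p = 0.00581) and H2-DMb1, a peptide exchange subunit, from 15.1 to 0.46 CPM (-5.02 ± 0.86, adjusted p = 0.0066). Of 20 antigen presentation genes, 10 fell and 0 rose (13 and 0 adjusted over the list alone; median -1.12; camera adjusted p = 7.41e-06; adjusted p = 0.455 with an estimated correlation). The list did not pass with fry (adjusted p = 0.0626). The set-adjusted count of genes lower was 4. Control replicate 2 carried much of the control means of these genes. Its Cd74 level was 867 CPM, against 142, 129 and 61.2 CPM in the other controls, and without this library the Cd74 log2 fold change was -3.94 (adjusted p = 0.00155). The list median was then -0.51, with 9 genes lower (camera adjusted p = 5.97e-06). The calls of H2-Aa (-4.31 ± 0.92), H2-Eb1 (-3.88 ± 0.79), H2-Ab1 (-3.76 ± 0.73) and Ciita (-3.73 ± 0.79), the class II transactivator, ended after set adjustment, with log2 fold changes of -4.03, -3.47, -3.43 and -3.19 and adjusted p between 0.081 and 0.12. The calls of H2-Aa and Ciita also ended without Ccna2-KO replicate 2 or 3 (adjusted p up to 0.0583 and 0.0554). Reads of H2 genes can be shared between close copies, so their individual values are uncertain. Of 40 interferon response genes, 3 fell and 1 rose (1 and 1 adjusted over the list alone), although the median was 0.28 and camera called the list as higher (adjusted p = 0.0231; adjusted p = 0.754 with an estimated correlation). Iigp1, an interferon-induced GTPase, changed by -3.89 ± 0.93, and Mb21d1, which encodes the DNA sensor cGAS, rose by 0.97 ± 0.16. The control mean of Iigp1 was carried by replicate 2 (71.7 CPM, against 2.88 to 13.3 CPM in the other controls). Without that library the Iigp1 log2 fold change was -2.27 (adjusted p = 0.0259). The Iigp1 call ended after set adjustment (-3.15, adjusted p = 0.20) and without any 1 of the libraries labelled Ccna2-KO (adjusted p up to 0.0829). The list call ended without control replicate 1 or 4 or Ccna2-KO replicate 4 (adjusted p up to 0.345). Without control replicate 2, which had the highest interferon list mean (0.83), 9 genes rose and 1 fell, with a median of 0.63 (camera adjusted p = 9.72e-06). Set-adjusted, 5 interferon genes rose and 1 fell.

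Stress and defence lists were split. Of 35 genes of oxidative stress and glutathione, 8 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.33; camera adjusted p = 8.90e-06; adjusted p = 0.315 with an estimated correlation), including Slc7a11, the cystine transporter (3.63 ± 0.46), and Akr1b8, an aldo-keto reductase (1.39 ± 0.16). Between 5 (without control replicate 4) and 21 (without control replicate 1) of them rose with single libraries left out. Of 23 antimicrobial genes, 8 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.57; camera adjusted p = 0.00158; adjusted p = 0.443 with an estimated correlation). Several were small proline-rich genes such as Sprr2a3 (1.42 ± 0.17), whose reads can be shared with near-identical copies. Of 30 immediate early and heat shock genes, 9 fell and 0 rose (11 and 1 adjusted over the list alone; median -0.58; camera adjusted p = 6.83e-05; adjusted p = 0.404 with an estimated correlation), including Nr4a1 (-1.52 ± 0.15). Of 30 genes of the unfolded protein and integrated stress responses, 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.404), with Psat1, of serine synthesis, at 2.06 ± 0.33. Of 22 inflammation genes, 1 rose, Cxcl5 (2.10 ± 0.52; adjusted p up to 0.0832 with single libraries left out, not passing without 6 of them, all but control replicate 1 and Ccna2-KO replicate 2), and 0 passed adjusted over the list alone (camera adjusted p = 0.657; set-adjusted, 4 rose and 0 fell). Of 25 cholesterol synthesis genes, 2 rose (2 adjusted over the list alone; median 0.27; camera adjusted p = 0.00188; adjusted p = 0.628 with an estimated correlation), and the set-adjusted call ended (adjusted p = 0.215). Without control replicate 1, 18 of these rose and 1 fell (median 0.56; camera adjusted p = 6.69e-07), and without any 1 of the other libraries 0 to 2 rose. Fatty acid oxidation (30 genes, 3 lower and 0 higher, 5 and 2 adjusted over the list alone) and tight junctions (25 genes, 2 lower and 1 higher, 2 and 1 adjusted over the list alone) were not called (adjusted p = 0.473 for each). Set-adjusted, 3 fatty acid oxidation genes rose and 2 fell, and 3 tight junction genes rose and 1 fell. The tight junction median was 0.0045 while its mean (-0.04) and camera direction were lower.

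Over the 33 lists tested, camera with its preset correlation of 0.01 called 18, of which 13 were higher and 5 lower. With an estimated correlation it called 0, with adjusted p between 0.112 and 0.993. The fry test, which asks whether the genes of a list move one way on balance, passed 16 lists, 13 of them among the 18. The called lists that did not pass fry included antigen presentation (adjusted p = 0.0626), antimicrobial defence (0.0584) and red blood cells (0.0708). Cholesterol synthesis (0.192) and interferon response (0.459) did not pass it either. Counts of genes moving in the direction of their list also varied with single libraries left out. The ranges were 9 to 17 for cyclins, 10 to 17 for p53 targets, 8 to 13 for fetal-like epithelium, 4 to 9 for the small intestine, 5 to 11 for antimicrobial defence and 0 to 5 for red blood cells, all higher. They were 8 to 12 for enteroendocrine cells, 10 to 13 for tuft cells, 16 to 19 for T cells, 5 to 12 for antigen presentation and 3 to 15 for immediate early genes, all lower. Among lists not called, the unfolded protein list ranged from 2 to 8 higher and 0 to 6 lower, and fatty acid oxidation from 0 to 2 higher and 1 to 7 lower. Camera with its preset correlation called 20 lists for genotype and 20 for the number set once the set term was in the fit. Lists higher in the high set included goblet (adjusted p = 3.77e-09), Paneth-like (0.000434), cholesterol synthesis (0.00168), stem cell (0.00176), tuft (0.0192) and enteroendocrine (0.0368) genes. Lists lower in the high set included tight junction (0.000965), interferon (0.00176) and immediate early (0.00215) genes.

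The genes named for the size of their change, all with a mean log2 CPM of at least 1, included matrix and secreted proteins. Ly6d, a surface antigen, had the largest rise among them, from 0.44 to 36.6 CPM (6.47 ± 0.84, adjusted p = 0.00193). Nid1, the basement membrane linker nidogen 1 on chromosome 13 (13437602 to 13512275), rose from 0.39 to 11.5 CPM (4.86 ± 0.30, adjusted p = 9.67e-05). Lama5, the laminin alpha 5 chain, rose from 11.9 to 137.9 CPM (3.54 ± 0.21, adjusted p = 9.67e-05). Atg9b (4.03 ± 0.44) and Pla2g2a, a transcribed pseudogene in the annotation used (3.85 ± 0.84), were also among the 10 highest, and the Pla2g2a call ended without control replicate 3 or Ccna2-KO replicate 3 (adjusted p up to 0.0560). Besides the class II genes and Iigp1, the 10 lowest held Gbp8, an interferon-induced guanylate-binding protein (-4.43 ± 0.63), Prlr, the prolactin receptor (-3.70 ± 0.29), and Gsdmc3, a gasdermin (-3.50 ± 0.24, from 145.5 to 12.9 CPM). Reads of Gbp8 and Gsdmc3 can be shared with close paralogs, so their values are uncertain.

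**Figure D4:**
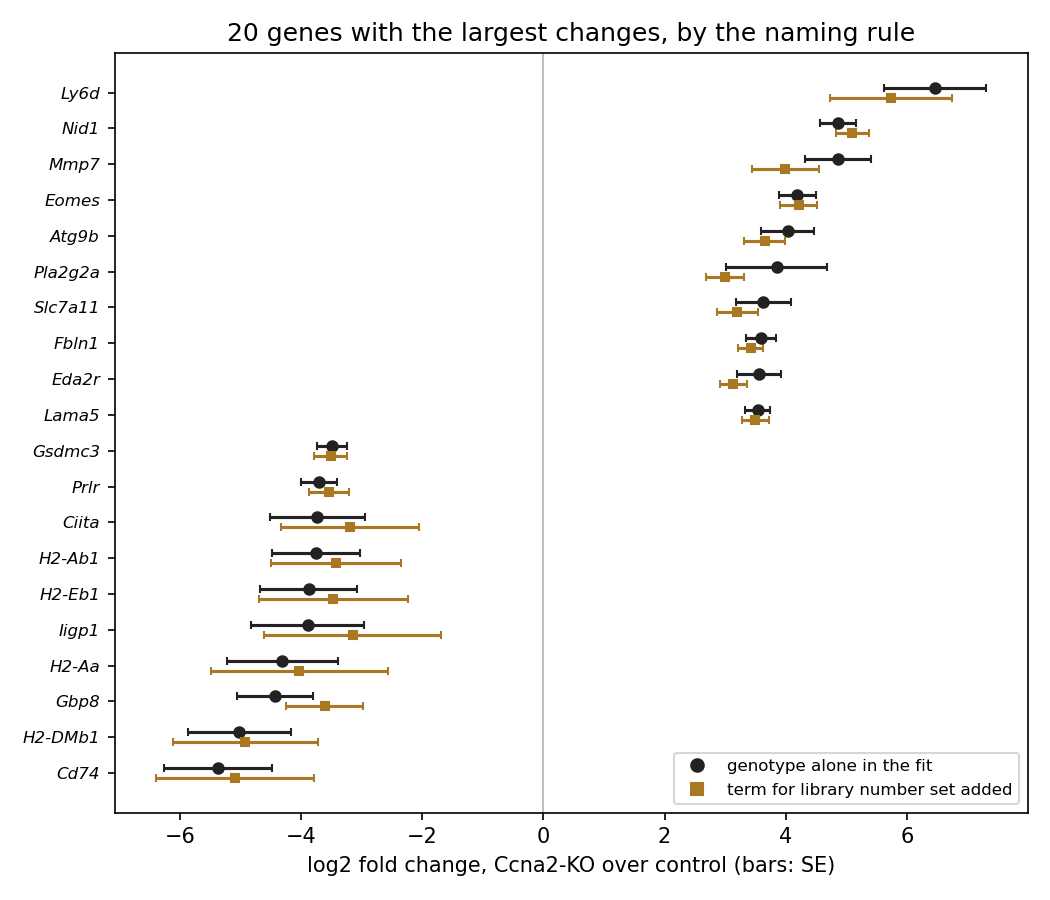
Log2 fold changes (x axis, libraries labelled Ccna2-KO over control, bars ± SE) of the 10 genes with the largest and the 10 with the smallest values under the naming rule, with genotype alone in the fit (circles) and with a term for the library number set (squares). Nid1 is at 4.86 ± 0.30 with genotype alone, and the squares lie on the same side of 0 as the circles for all 20 genes.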

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

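The tests of the Ccna2 level and of the T cell genes, and the set-adjusted values, were chosen after the results were seen. The count of other splits was written before. The rule for the clock genes is also marked as written before. The clock lists, however, are among those chosen after seeing the data, so that test is not independent of them.

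Chance cannot be excluded for the number of changed genes by the count of other splits. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 1924 genes of genotype (5.71%), and the highest other split gave 1949. The rule written before set the limit at 5% but added that 1 other split of the 35 would still be under it. These 2 parts conflict, since 2 of 35 is 5.71%, and the 5% limit was used. That other split follows the library numbers, with control replicate 1 beside Ccna2-KO replicates 1 to 3 and Ccna2-KO replicate 4 beside the other controls. The remaining 33 splits gave at most 2 genes, and 32 of them gave 0. These counts point to a structure of the samples that overlaps with genotype. With a term for the number set, 2892 genes changed with genotype. Whether the sets stand for litters, days or preparations is not given in the sources used here, and genotype and set share 6 of 8 libraries.

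Ccna2 did not separate the groups, and its lower mean in the libraries labelled Ccna2-KO did not pass. For a swap of some libraries between the groups, other than control replicate 1 with Ccna2-KO replicate 4, no split needed gave more than 2 genes. That count could speak against such a swap only if genotype changes many genes. This is not known apart from the labels, so the count does not decide on it. A swap of control replicate 1 with Ccna2-KO replicate 4 gives the division along the library numbers with its 1949 genes. These 2 libraries lay nearest to 0 on the first principal component, at -8.80 and 28.1. With these labels exchanged, Ccna2 was higher in the Ccna2-KO group by 0.7333 ± 0.40 (SE, log2 CPM), which did not pass (exact permutation p = 0.0857). The exchange moves control replicate 1, with the highest Ccna2 level, into that group, so this value does not decide on the swap. Whether these 2 libraries were swapped stays open, and so does an exchange of the whole groups, with or without these 2. The log2 ratio of Ccna2 to the mitosis list mean runs the way the labels say, at 0.33 to 1.22 in the controls and -0.45 to -0.26 in the libraries labelled Ccna2-KO (exact permutation p = 0.0286). It was formed after both of its parts had been seen and follows from them, so it does not decide on these exchanges. More cycling cells with a lower Ccna2 level in each stay open for the same reason, since the level per cycling cell was not measured. Incomplete recombination, non-epithelial cells and reads from exons left in place also stay open, as untested.

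T cell genes were lower by a median of -2.57. A loss that lowered all lists of blood-derived cells by as much as the T cell list is argued against. The lowest median among the B cell, macrophage, neutrophil and red blood cell lists was -0.3846 (quartiles -0.73 and -0.01, macrophage list). Neutrophil and red blood cell medians were 0.29 and 1.71. Only 5 of 21 B cell genes and 7 of 17 neutrophil genes could be tested, so their lists say little about a loss of these cells. Some genes of antigen-presenting cells and of leukocytes at large fell about as far as the T cell genes, such as Cd74 (-5.38), Ciita (-3.73), Ptprc (-2.63) and Laptm5 (-2.20). A loss of other leukocytes therefore stays open. The T cell list also differed between the number sets (adjusted p = 0.000179). The sets as the whole cause are argued against, since with a set term the median for genotype was -1.93, with 16 genes lower. Camera with its preset correlation still called the list (adjusted p = 2.83e-08). The set term rests on control replicate 1 and Ccna2-KO replicate 4, so effects of these single libraries cannot be told from a set effect. Whether the isolates held fewer T cells or T cells expressed these genes at lower levels was not tested, and genotype and cell isolation both stay open as the origin.

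Clock genes of a list chosen after seeing the data were lower, 5 of 8 past the threshold, with a median log2 fold change of -1.18. Those passing were Per1, Per2, Per3, Nr1d1 and Ciart, whereas Dbp, Tef and Nr1d2 did not pass. Between 3 (without control replicate 2) and 6 (without control replicate 1) fell with single libraries left out. A difference in time of day of tissue collection would also raise Arntl, Npas2, Clock and Nfil3. Their median was 0.2382 with a standard error of 0.19 and 0 of 4 passed, which lies between the values written for and against that cause, so it stays open. With the set term their median was 0.55 and 2 of 4 passed, which goes with that cause in a fit chosen after seeing the data.

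In 19 of 272 groups of 4 libraries, 1 library lay far from the other 3 on a named gene, a list mean or a library measure, where chance gives about 1 in 20. Values are the gap to the nearest library over the range of the group. Control replicate 1 was the highest control for Rrm2 (0.933), Pola2 (0.858), E2f7 (0.888), Car2 (0.854) and Retnlb (0.934), and for the list means of DNA replication (0.924), DNA damage and repair (0.869) and oxidative stress (0.889). The lowest control was replicate 2 for Chgb (0.938) and Akr1b8 (0.846), replicate 3 for Cbr3 (0.903), and replicate 4 for Polq (0.836). Control replicate 3 was the highest for the fibroblast list (0.904). Among the libraries labelled Ccna2-KO, replicate 1 was the highest for Pecam1 (0.949), Egr3 (0.86) and the fibroblast list (0.869), and replicate 3 for Cbr3 (0.965). Replicate 4 was the lowest for Gja1 (0.887) and the highest for the share of counts without a gene symbol (0.867). Among 60 tested transcripts without a symbol, outside the gene tests, 3 were higher and 7 lower in the libraries labelled Ccna2-KO.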

How the results depend on the processing

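The set-adjusted fit and the list counts with single libraries left out were chosen after seeing the data, and the other alternatives before. The number of changed genes stayed within 1.5 times of 1924 under RLE and upper quartile scaling, no filter, the stricter filter, voom and non-robust estimates (1700 to 1967). DESeq2 gave 2901 genes (1408 lower), a 2-fold minimum 1131, single transcripts 357, and the set-adjusted fit 2892 (1415 lower). With the replicate block, 987 genes changed (619 higher, 368 lower). No pairing by replicate number was seen in the deviations from the group means. Those of same-numbered libraries correlated at -0.07, -0.35, -0.26 and 0.15, and 0 of 4 libraries correlated best with their own number. These few values cannot exclude a pairing, and the library numbers of replicate 1 (632 and 633) and replicate 4 (598 and 597) are adjacent. Leaving out single libraries gave 972 to 4627 genes (572 to 2457 higher, 400 to 2170 lower). The highest came without control replicate 1, which leaves all controls in the low number set, and the lowest without Ccna2-KO replicate 3. The Ccna2 log2 fold change lay between -0.58 and 0.24 with single libraries left out, positive without control replicate 1 and negative in the other 7 fits.

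For the 100 other named genes, 1554 of 1692 values under the alternatives kept their direction and side of the threshold, 122 no longer passed, 13 newly passed and 3 changed sign. These were Cdk2 (-0.10) and Ccna1 (-0.11) with the set term and Muc2 without Ccna2-KO replicate 4 (-0.29 to 0.092 over the left-out libraries), none of them passing. With an estimated correlation 0 lists were called, against 18. Among single lists, 416 of 492 values kept direction and call, 36 no longer passed, 23 newly passed and 17 changed direction. The goblet cell list did so without a filter (adjusted p = 0.999532), with the stricter filter (0.998636), with the replicate block (0.987), with fry (0.985), with the set term (0.00725) and with 5 of the libraries left out (0.173 to 0.978 over all 8). The set term also turned the B cell (0.80), fatty acid oxidation (0.742) and tight junction (0.415) lists. Leaving out single libraries turned the B cell list (0.385 to 0.978) and the inflammation list (0.233 to 0.966). Apart from the goblet list with the set term, none of these passed. The cause of these differences was not tested. With 4 libraries per group, changes of 2-fold are often missed, as in the simulation.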

Other observations

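The gene groups given here were chosen after the data were seen, so their counts describe these libraries and are not independent tests. Of 3 gasdermin C genes, all 3 fell, with a median log2 fold change of -2.61 (Gsdmc2 -2.61, Gsdmc3 -3.50 and Gsdmc4 -2.32), and their reads can be shared between copies. Of 13 interferon-inducible GTPases, 7 fell and 0 rose, with a median of -2.07, including Gbp4 (-3.31 ± 0.62) and Tgtp2 (-3.21 ± 0.60), while Irgm1 was at -0.48 ± 0.33 and did not pass. Their median was -1.25, with 6 lower, without control replicate 2, and 3 fell after set adjustment (median -1.62) or without Ccna2-KO replicate 2. Of 10 carboxylesterases, 5 fell and 0 rose, led by Ces1d (-1.78 ± 0.18). Between 3 and 6 carboxylesterases fell and 0 to 2 rose with single libraries left out.

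Of 8 genes of serine and one-carbon synthesis, 3 rose and 0 fell. Phgdh and Psat1, of the first steps of serine synthesis, each rose by 2.06 (SE 0.49 and 0.33), and Mthfd2 rose by 1.23 ± 0.31, whereas Psph was at -0.01 ± 0.19. The cystine transporter Slc7a11, grouped with these 8 in the counting, rose by 3.63 ± 0.46. Of all 9, 2 rose without any 1 of control replicates 2 to 4 or Ccna2-KO replicates 1 to 3, and 6 without control replicate 1. Of 15 basement membrane genes, 4 rose and 0 fell (7 and 1 set-adjusted). Nid1 (4.86 ± 0.30) and Lama5 (3.54 ± 0.21) rose most with Fbln1 (3.59 ± 0.24), while Lamb2 was at 0.08 ± 0.32, Nid2 at -0.40 ± 0.13 and Hspg2 at -0.46 ± 0.23, and these 3 did not pass. Set-adjusted, Nid1, Lama5 and Fbln1 were at 5.10, 3.50 and 3.42.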
